A study of Homo sapiens with 8 samples.

How the data were processed

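HAP1 is a near-haploid human cell line derived from a chronic myelogenous leukaemia, in which most genes are present as a single copy. Wild-type HAP1 cells were compared with 1 clone, clone 11, in which BCDIN3D had been knocked out. Per the labels' protocols, the cells grew for 48 h in medium with 10% serum, RNA of an integrity number of 10 was extracted, and the same RNA went into stranded total RNA libraries and into small RNA libraries. There were 8 libraries: 2 wild-type and 2 knockout libraries in each of the 2 assays. Replicate 1 of every group carries the date 2018-5-6 in its label and replicate 2 the date 2018-5-9, and the series' design text calls them biological replicates. The labels do not say whether the replicates came from independently thawed cultures, so p-values measure the spread between these samples, which may in part be technical. Since there was 1 knockout clone, differences between clones and effects of the lost gene were not separable in any comparison.

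The authors deposited raw counts: 1 file per library with a whole-number read count per gene symbol (57996 symbols) or per mature microRNA name (2656 names). The submitters' processing notes name FastQC, cutadapt, STAR, SAMtools, featureCounts and Subread, and hg38 as the genome build, without roles. Their versions, the annotations and the strand setting of the counting are not given in the sources used here. No normalisation had been applied to the deposited counts, whose totals differed between libraries. The microRNA files also held 1 row named with an asterisk, which had 0 counts and was left out. Reads that fit several copies of a gene may be split or dropped by such counting, so values of genes with near-identical copies are uncertain. Only some of these genes are marked as such where they appear. In the microRNA files, 14 of the 412 rows with 40 or more counts over the 4 libraries held the same counts as another row in every library, among them miR-103a-3p and miR-103b, and miR-423-5p and miR-3184-3p, which lie on opposite strands of 1 locus.

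Total counts per library were 20728819 and 24415272 in wild-type and 21416336 and 20065041 in knockout for RNA-seq. The small RNA libraries held 236073 and 266466 microRNA counts in wild-type and 157706 and 346626 in knockout. A single small RNA count was therefore worth several CPM, and precision there was low. The replicates of each group differed by more than sampling noise: the chi-square per degree of freedom was 3.62 and 4.37 for RNA-seq and 19.1 in both small RNA groups. No library was counted as a duplicate of another. The biological coefficient of variation was 5.53% for RNA-seq and 109% for small RNA. Intervals and floors cover counting error only, since the reads carried no molecular identifiers.

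Counts were analysed in R 4.3.3 with edgeR 4.0.16, each assay in its own fit. Rows were kept by filterByExpr (minimum count 10), which left 16233 genes and 546 microRNAs. Normalisation used TMM, and knockout was tested against wild-type with the robust quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over all rows tested, with a threshold of 0.05. All adjusted p-values of single genes and microRNAs come from this edgeR fit unless another tool is named. A standard error of a log2 fold change was taken as its size divided by the square root of F. CPM, the counts scaled to a common library total, use the TMM-scaled library sizes, and group values are means with SD over n = 2 libraries. Where a group had 0 counts, the fold change is given as a lower bound against 3 counts over the group. With 1 to 3 counts in a group, the ratio of counts is given with its exact 95% interval. Gene positions came from a RefSeq table of GRCh38.p14, matched by symbol or by an unambiguous older symbol. Of the tested genes 14223 (87.6%) had a position.

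Before the data were examined, 38 gene lists, 24 microRNA families, 35 pairs of microRNA and host gene and the test designs were fixed. The rule for named genes was fixed then too. It took BCDIN3D, then the 12 largest rises and the 12 largest falls among called genes with a gene symbol, a mean of at least 1 CPM and the same direction at both dates. It also took, for each list described, up to 2 called members each way, or up to 2 of smallest p where none was called, and ALDOC, DICER1, DROSHA, LIN28B, HMGA2, HARS1 and MEPCE whatever their p. For microRNAs it took up to 8 called each way with a mean of at least 10 CPM, let-7 members with a mean of at least 1000 CPM, miR-145, miR-23b and the 3 most abundant microRNAs. Of the let-7 family 0 members reached that mean. Outside the rule, and after their values were seen, the text also names KRT18, ESRP1, VIM, PFKM, HIST1H3C, SMN2, GTF2H2C, FRMD5, CATSPER2P1, the protocadherin genes, GALNT13, GALNT14, GALNT16, let-7a-5p, miR-140-3p, miR-21-5p and miR-200a-5p. Other genes named outside it are said to be so where they appear.

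Gene lists with at least 5 tested members (37 of 38) and families with at least 3 (12 of 24) were tested with camera in limma 3.58.1, with a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Median log2 fold changes of chromosomes, and of 534 windows of 50 neighbouring tested genes, were set against 10000 random gene lists of the same size. Successive windows on a chromosome shared part of their genes. The host gene correlation used 100000 permutations. Alternatives were DESeq2 size factors, library size alone, no filter and a stricter filter on low counts, DESeq2 1.42.0, the date as a block, removal of a trend with gene span, and leaving out each library in turn. Where that left 1 library in a group, this library was assumed to vary like those of the other group.

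The shared date pairs the libraries of both genotypes. Differences between the dates correlated between wild-type and knockout with r = 0.08 over the RNA-seq genes and r = -0.09 over the microRNAs. The fit without the date block was the main one, with 2 residual degrees of freedom. The date block left fewer, so blocked p-values depend strongly on the estimated spread and are given as an alternative only.

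The scripts were tested on simulated data drawn from the real means, library sizes and dispersions. For the RNA-seq comparison, with 16233 genes and 200 of them changed, the test recovered 59.7% of 1.5-fold, 82.1% of 2-fold and 90.9% of 4-fold changes. Over 20 draws of that simulation, false calls made up 1.89% to 12.9% of the calls (median 6.58%), so the share of false calls could exceed the nominal 5%. For the small RNA comparison, with 546 microRNAs and 60 of them changed, it recovered 0% of 1.5-fold, 0% of 2-fold and 5% of 4-fold changes. The list test gave an adjusted p of 1.36e-30 for a planted list of 25 raised genes and 0.548 or more for random lists. With an estimated correlation the planted list had an adjusted p of 0.0226. These adjusted values cover the simulated lists alone, not the larger number of lists tested in the data. The value of 0.0226 therefore does not show that such a list would pass among the real lists with an estimated correlation. Of 6 windows past the threshold in a simulation with 1 raised region, 3 overlapped that region.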

Results

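Gene expression and microRNA levels were measured in HAP1 cells with and without BCDIN3D, a methyltransferase that modifies the 5′ end of histidine tRNA and has been linked to the processing of microRNA precursors. RNA-seq and small RNA-seq each covered 2 wild-type and 2 knockout libraries, with RNA shared between the assays. RNA-seq depth lay between 20065041 and 24415272 counts per library. The small RNA libraries held 157706 to 346626 microRNA counts.

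The targeted gene was lower in the knockout libraries. BCDIN3D (chromosome 12, 49836043 to 49843106, GRCh38) stood at 7.40 and 4.90 CPM in the wild-type libraries and at 1.56 and 2.71 CPM in the knockout libraries. Its log2 fold change was -1.52 ± 0.24 (SE, adjusted p = 2.06e-05). The transcript was thus still counted in the knockout clone, and counts per gene do not show which exons the reads came from.

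Of the 16233 tested genes 1065 differed between the knockout clone and wild-type cells, 497 higher and 568 lower in knockout, all with the same direction at both dates. Large changes were mostly falls: 118 genes were at least 8-fold lower by the fitted fold change and 8 at least 8-fold higher. At 2-fold the numbers were 324 and 72. With the date as a block 767 genes were higher and 784 lower, and DESeq2 called 255 higher and 331 lower. Scaling by library size alone moved the share of calls that were higher from 46.7% to 36.7%. Leaving out any library except knockout replicate 1 lowered the number of calls. Without wild-type replicate 1 there were 246 higher, without wild-type replicate 2 there were 327 higher and 367 lower, and without knockout replicate 2 there were 307 higher.

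Several transcripts that were readily counted in wild-type cells were at or near 0 in the knockout clone. SETBP1, which encodes a nuclear protein binding the SET oncoprotein, had 255 counts in the wild-type libraries and 0 in the knockout libraries, at least 76.7-fold lower. The thiamine transporter gene SLC19A3 (172 counts in wild-type) was at least 51.7-fold lower, DCAF12L2 (152 counts) at least 45.7-fold, the gap junction gene GJA1 (132 counts) at least 39.7-fold and BRINP3 (107 counts) at least 32.2-fold, all with 0 counts in knockout. MGMT, which encodes the repair enzyme for O6-methylguanine, fell from 427 counts to 1, a ratio of 385 (95% interval 68.7 to 15246). PTPRN2 had 350 counts against 1, a ratio of 316 (56.3 to 12503). The enamel matrix gene AMBN had 1098 counts against 1, a ratio of 990 (177 to 39148), but its wild-type libraries differed widely (23.5 ± 9.78 CPM) and its adjusted p was 0.0257.

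FASTKD2, whose product acts in mitochondrial RNA metabolism, went from 18.0 ± 3.92 to 0.0991 ± 0.0732 CPM (log2 fold change -7.45 ± 0.33). The collagen gene COL11A1 went from 19.1 ± 2.40 to 0.146 ± 0.0063 CPM (-6.97 ± 0.29) and the mucin-type glycosyltransferase gene GALNT5 from 13.0 ± 1.42 to 0.101 ± 0.142 CPM (-6.98 ± 0.36). GTF2H2, a subunit gene of the general transcription factor TFIIH, had 223 counts in wild-type and 1 in knockout, a ratio of 201.1 (95% interval 35.7 to 7979). It lies in a duplicated region of chromosome 5 with near-identical copies, so its value is uncertain. In the same region SMN1, chosen after its values were seen, had a log2 fold change of -1.38 ± 0.18, while its near copy SMN2 gave 0.13 ± 0.26 and the GTF2H2 copy GTF2H2C -0.06 ± 0.13.

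**Figure D1:**
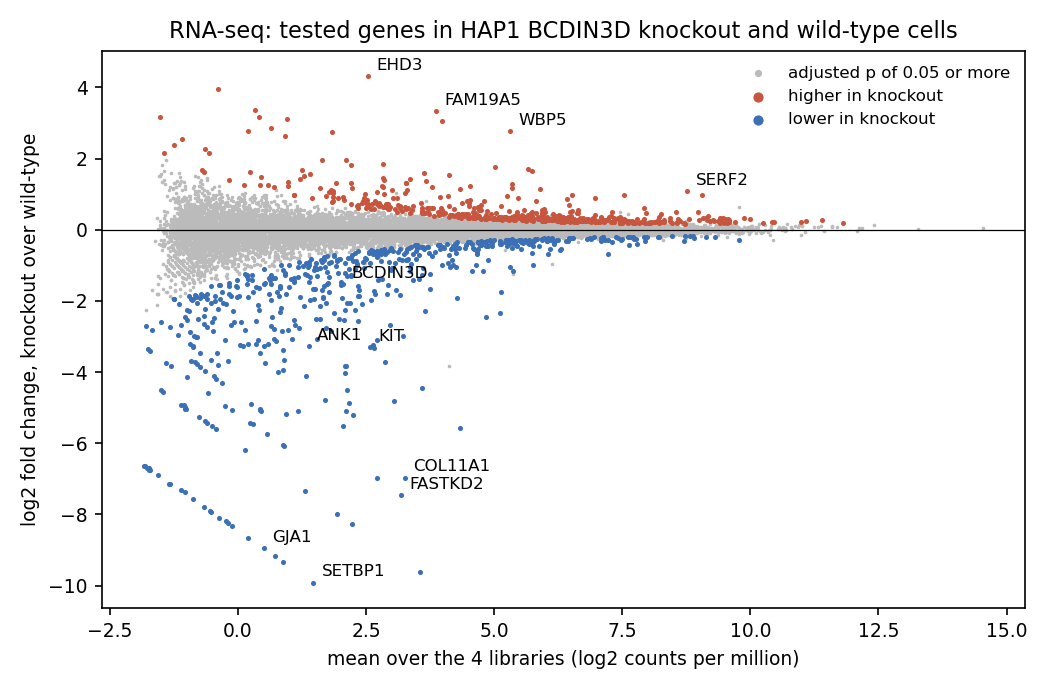
Log2 fold change of each tested gene (knockout over wild-type, vertical axis) against its mean over the 4 RNA-seq libraries (log2 CPM, horizontal axis), with the 497 higher and 568 lower genes coloured and a few genes named. The diagonal rows of points at the lower left are genes with 0 or 1 count in knockout, whose fitted values depend on the prior count and are not bounds.

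Among the genes that rose, EHD3, which encodes an endosomal recycling protein, was highest in fold. It went from 0.548 ± 0.0271 to 11.1 ± 1.17 CPM (log2 fold change 4.32 ± 0.25, adjusted p = 5.16e-19). FAM19A5 (now TAFA5), which encodes a secreted brain-enriched protein, rose from 2.64 ± 0.0079 to 26.6 ± 0.393 CPM, a log2 fold change of 3.33 ± 0.15. A pair of small X-linked genes rose by similar amounts: FAM127C (now RTL8B) by 3.05 ± 0.15 and WBP5 (now TCEAL9) by 2.78 ± 0.10, the latter from 10.0 ± 0.340 to 68.9 ± 6.05 CPM. The GDNF receptor gene GFRA1 rose by 3.37 ± 0.47 and the mesenchymal transcription factor gene TWIST2 by 3.12 ± 0.35. The receptor gene EPHA10 (2.75 ± 0.27), the homeobox gene NKX2-4 (1.97 ± 0.25), the neuronal gene ATCAY (2.77 ± 0.44), NOL4 (2.63 ± 0.38), the antisense transcript BBOX1-AS1 (2.86 ± 0.38) and the noncoding RNA LINC01388 (3.17 ± 0.47) were the others among the 12 largest rises. The LINC01388 call was lost with DESeq2 (adjusted p = 0.113).

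The 7 genes of known or proposed pathways of BCDIN3D that had been fixed by name missed the threshold. Glycolytic aldolase ALDOC had a log2 fold change of -0.27 ± 0.17 (adjusted p = 0.475). The microRNA-processing ribonucleases DICER1 (0.02 ± 0.06) and DROSHA (-0.19 ± 0.08, adjusted p = 0.173), the let-7 regulators and targets LIN28B (-0.08 ± 0.07) and HMGA2 (0.01 ± 0.07), histidyl-tRNA synthetase HARS, now HARS1 (-0.05 ± 0.07), and the 7SK capping enzyme MEPCE (0.15 ± 0.08, adjusted p = 0.318) also missed the threshold. MEPCE passed it without knockout replicate 1 (adjusted p = 0.0104). Among 28 genes of the microRNA machinery, 0 were higher and 1 was lower, LIN28A (-0.45 ± 0.12), which lost its call with DESeq2. Among 32 genes for histidine tRNA and tRNA processing, only the splicing endonuclease subunit gene TSEN15 was called, as lower (-0.24 ± 0.07), and that call was lost with DESeq2. With the date as a block SSB was lower as well (blocked adjusted p = 0.00842) and RNH1 higher (blocked adjusted p = 0.0414), both chosen after their values were seen. Of 20 tRNA synthetase genes only EPRS was lower (-0.30 ± 0.06). TSEN15 and EPRS both lie on the long arm of chromosome 1, which is described further on.

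Replication-dependent histone genes rose together. Of 26 measured members 23 were higher and 1 lower in knockout, and the median log2 fold change was 0.26. Adjusted over the list alone, 24 were higher and 1 lower. The largest rise was that of HIST1H3A (0.49 ± 0.06), followed by HIST1H2BJ (0.34 ± 0.06). HIST1H2BB was lower (-1.42 ± 0.39), a call lost with DESeq2. The list's adjusted p was 8.42e-17 with camera at a preset correlation and adjusted p = 0.835 with an estimated correlation. The histone genes carry an estimated correlation of 0.41 between them, and many are near-identical copies, so their counts are not independent. The epithelial and YAP lists described below lost the threshold too, though their estimated correlations (-0.01 and -0.06) lay below the preset 0.01. Correlation between genes does not account for their loss. The fit had only 2 residual degrees of freedom, so a list that fails with an estimated correlation is not shown to be unchanged. Of 33 G1/S genes and 34 G2/M genes 0 were called in either direction, with 0 also adjusted over the list alone. With the date as a block 3 G2/M genes were higher, PRC1 (blocked adjusted p = 0.0219), CDC20 (blocked adjusted p = 0.0471) and KIF20A, and 2 were lower, MKI67 and CKAP2L. KIF20A, MKI67 and CKAP2L were chosen after their values were seen.

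**Figure D2:**
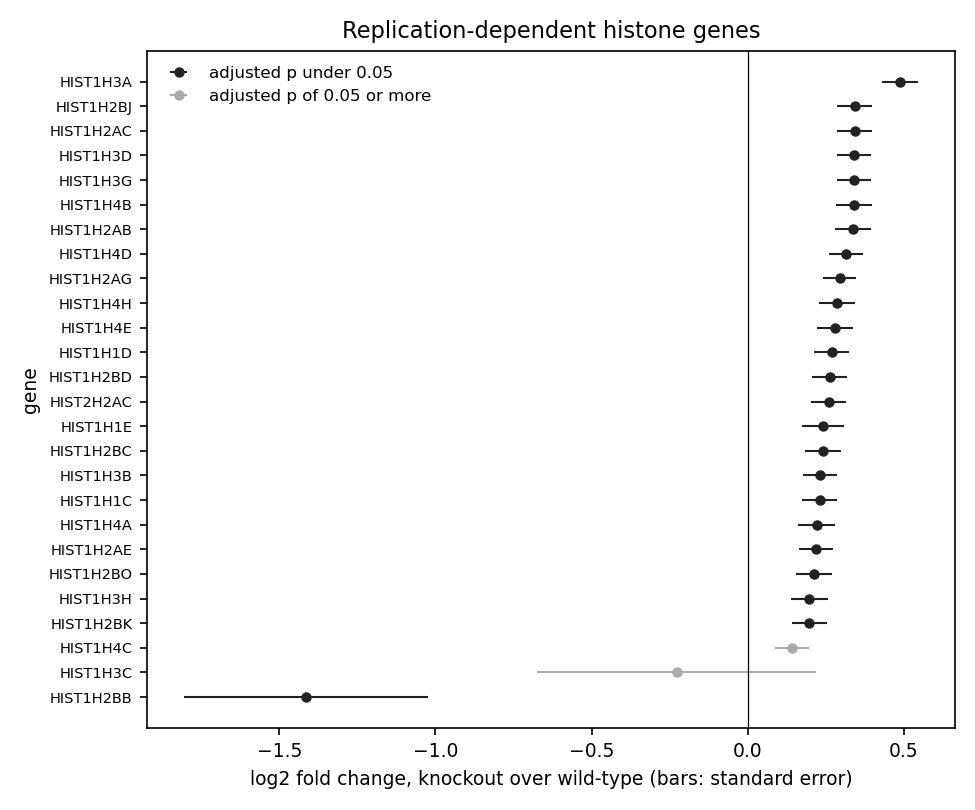
Log2 fold change (knockout over wild-type, horizontal axis) of each of the 26 tested replication-dependent histone genes, with bars for the standard error and black points for adjusted p under 0.05. All but HIST1H3C and HIST1H2BB lie above 0.

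Cell-identity genes shifted in both directions. Of 11 epithelial markers 0 were higher and 4 lower: EPCAM (-2.29 ± 0.59), the keratins KRT8 (-1.08 ± 0.14) and KRT18, and the splicing regulator ESRP1. Camera gave an adjusted p of 4.2e-03 with the preset correlation and adjusted p = 0.835 with an estimated correlation. The EPCAM call was lost with DESeq2. Among 18 mesenchymal genes 3 were higher, TWIST2, SPARC (0.32 ± 0.07) and VIM, and 1 was lower, PRRX1, with 119 counts in wild-type and 3 in knockout, a ratio of 35.8 (95% interval 11.9 to 176). The list's adjusted p was 0.0817. Of 17 targets of the YAP pathway 4 were higher and 0 lower, with TGFB2 (0.75 ± 0.19) and RBMS3 (0.74 ± 0.18) highest (adjusted p = 4.9e-03, and adjusted p = 0.835 with an estimated correlation). Both of these calls were lost with DESeq2. Of 5 blood cell markers 1 changed, the stem cell factor receptor gene KIT, which fell by 3.30 ± 0.23 on the log2 scale. That list's adjusted p was 4.9e-03 and adjusted p = 0.835 with an estimated correlation.

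Of 9 neural markers 1 was higher and 4 were lower, with falls in SYT1 (-1.32 ± 0.29) and PAX6 (-0.82 ± 0.15) and a rise in OLIG2 (0.49 ± 0.13), and the list's adjusted p was 0.112. The calls of SYT1 and OLIG2 were lost with DESeq2. Among 16 fibroblast and matrix genes 3 rose and 3 fell, with FBN1 at 0.47 ± 0.08 and LAMA4 at -1.14 ± 0.17. Among 26 HOX genes 4 rose and 2 fell, with HOXD13 at 0.84 ± 0.11 and HOXC10 at -1.36 ± 0.29. Among 29 immediate early genes the pluripotency factor gene KLF4 fell by 2.09 ± 0.21, and DUSP4 and CYR61 were higher.

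Targets of microRNAs that have been tied to BCDIN3D were tested as lists. Of 35 let-7 targets 1 was higher (THBS1, 0.90 ± 0.17) and 7 lower, led by CCND1 (-0.89 ± 0.26) and GATM (-0.84 ± 0.12). The list's adjusted p was 0.112, and the CCND1 call was lost with DESeq2. Of 24 miR-145 targets 2 were higher and 3 lower, among them IRS1 (0.61 ± 0.13) and FLI1, which had 47 counts in wild-type and 3 in knockout, a ratio of 14.1 (95% interval 4.55 to 71.0). The list's adjusted p was 0.599. Since miR-145-5p had 0 counts in wild-type and knockout libraries alike, this list says little about a change of that microRNA. Of 10 nuclear-retained RNAs 0 were higher and 2 lower, the noncoding RNAs NEAT1 (-0.46 ± 0.08) and MALAT1 (-0.28 ± 0.06). That list's adjusted p with camera was 0.289. Among 25 glycolysis genes 3 were higher, ENO2 (0.46 ± 0.07), PFKL and PFKM. Of 19 unfolded protein response genes only PDIA3 was called. With the date as a block CALR was higher as well (blocked adjusted p = 0.0271), and HSPA5 (blocked adjusted p = 0.0107) and SEC61B (blocked adjusted p = 0.0190) were lower, all 3 chosen after their values were seen. That list had an adjusted p of 0.0321 and adjusted p = 0.835 with an estimated correlation, and PDIA3 lies in the chromosome 15 block described further on. The block on the date also added calls in other lists: 6 YAP targets and 4 mesenchymal genes were then higher, 5 fibroblast and matrix genes higher and 3 lower, 4 glycolysis genes higher and 1 lower, and 2 immediate early genes higher and 2 lower.

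MicroRNA counts were dominated by a few names. The 3 most abundant were miR-3168, at 39.1% ± 6.16 of counts in wild-type and 31.8% ± 0.961 in knockout (SD, n = 2), miR-30d-5p, at 18.8% ± 4.99 and 24.6% ± 1.31, and miR-8052, at 6.24% ± 0.320 and 6.08% ± 0.0135. Their log2 fold changes were -0.55 ± 0.21, 0.12 ± 0.26 and -0.29 ± 0.23, each with an adjusted p of 0.999. With the date as a block miR-3168 passed the threshold (blocked adjusted p = 0.00459), though its log2 fold change stayed at -0.55.

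Both arms of miR-486, a microRNA abundant in erythroid and muscle cells, fell in knockout. miR-486-5p went from 37100 ± 5138 to 4477 ± 867 CPM (log2 fold change -3.05 ± 0.30, adjusted p = 0.0113). miR-486-3p went from 10579 ± 548 to 1333 ± 260 CPM (-2.99 ± 0.33, adjusted p = 0.0115). The ankyrin gene ANK1, in which miR-486 lies (chromosome 8, 41653225 to 41896741), was chosen after its values were seen. In RNA-seq it went from 4.71 ± 0.954 to 0.491 ± 0.159 CPM (-3.26 ± 0.32, adjusted p = 4.00e-11). Both arms also passed the threshold with DESeq2 (adjusted p = 5.22e-23 for miR-486-5p and 6.86e-18 for miR-486-3p). They did so under every other alternative that kept all libraries. Both calls were lost when wild-type replicate 1 or wild-type replicate 2 was left out, which left 1 wild-type library. The log2 fold changes of miR-486-5p in those fits were -2.83 and -3.18.

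**Figure D3:**
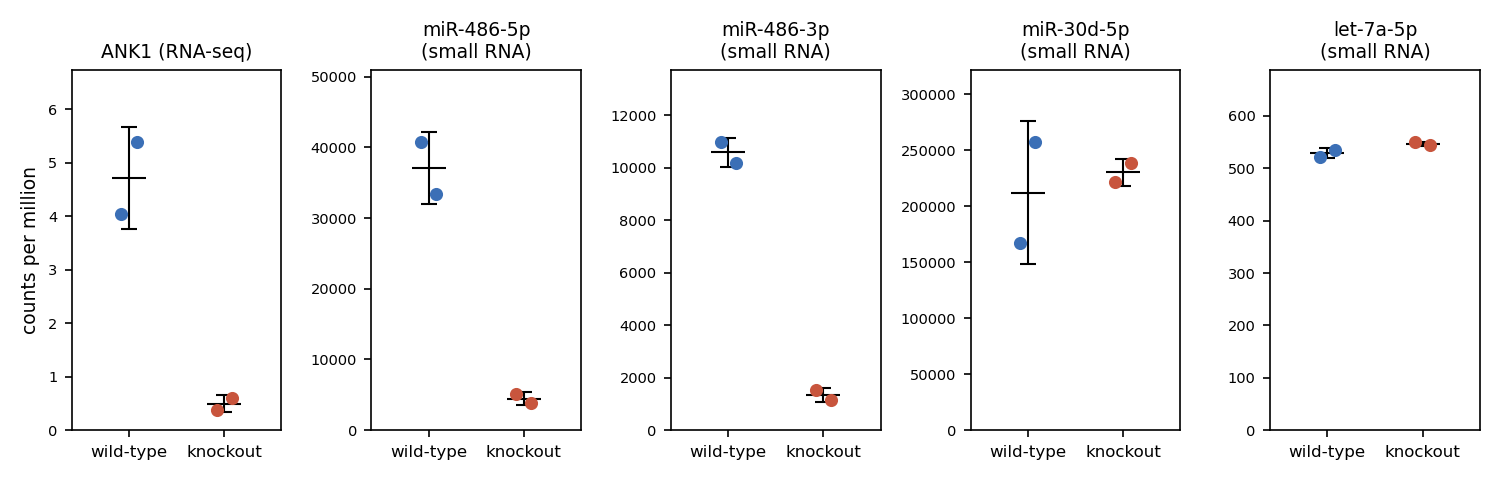
Levels in CPM (vertical axes, each starting at 0) of ANK1 in RNA-seq and of 4 microRNAs in small RNA-seq, with points for single libraries and bars for mean ± SD (n = 2). ANK1 and both arms of miR-486 are lower in both knockout libraries, while miR-30d-5p and let-7a-5p overlap or lie close between the groups.

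These were the only 2 of 546 microRNAs called by edgeR, with 0 higher and 2 lower. At an unadjusted p under 0.05 there were 11, and DESeq2 called 2 higher and 3 lower. With the date as a block 2 were higher and 4 lower. In small RNA data simulated from these libraries 5% of 4-fold changes were recovered. That share rests on a single draw of 20 microRNAs with such a change, taken from all 546 whatever their abundance. It is thus no estimate for the abundant ones. miR-30a-5p, chosen after its values were seen, went from 14768 ± 4534 to 4757 ± 1038 CPM (log2 fold change -1.63 ± 0.35). It missed the threshold (adjusted p = 0.417) but passed it with the date as a block (adjusted p = 3.62e-09) and with DESeq2 (adjusted p = 0.000131). With the block its log2 fold change was -1.62, so the smaller p came from the estimated spread and not from a larger effect.

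The microRNAs linked to BCDIN3D gave few counts. miR-145-5p had 0 counts in all 4 libraries, and miR-145-3p had 9 counts in wild-type replicate 2 and 0 elsewhere. miR-23b-3p had 6 and 24 counts in wild-type and 5 and 1 in knockout, too few to be tested. The let-7 family took 0.129% ± 0.0208 of counts in wild-type and 0.153% ± 0.00104 in knockout, and its most abundant member let-7a-5p stood at 529 ± 9.52 and 547 ± 4.01 CPM (0.05 ± 0.47, adjusted p = 0.999). Of 12 families tested 0 passed the threshold, and let-7 had an adjusted p of 0.856.

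MicroRNAs and the genes that host them showed no detectable relation in their fold changes. Across 22 host genes Pearson's r was -0.18 (permutation p = 0.315) and Spearman's rho was -0.19 (permutation p = 0.402), both two-sided. Without the 2 host genes of most extreme fold change r was -0.40. This is a correlation across genes, which are not independent replicates. Most host genes hardly changed and the microRNA values were imprecise, so the correlation had little power to show a relation. miR-103a-1-5p and miR-103a-2-5p also entered as separate pairs with identical counts. The ubiquitin ligase gene WWP2 fell by 1.76 ± 0.10 on the log2 scale, while miR-140-3p, which lies in it, had 0.37 ± 0.33 (adjusted p = 0.999). The other called host gene, VMP1, fell by 0.29 ± 0.08, and miR-21-5p, which lies in it, had -1.08 ± 0.59 (adjusted p = 0.999). miR-486 and ANK1 were not among the pairs fixed beforehand.

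Neighbouring genes moved together in parts of the genome. Whole chromosomes shifted little: 11 of 23 medians passed the threshold, but the largest was 0.04 on the log2 scale. Of 534 windows 35 were lower and 24 higher. Successive windows overlapped, so their counts are not independent, and the random lists did not allow for correlation between neighbours. On chromosome 1 the long arm stood out, with 19 of its 23 windows lower. The median log2 fold change was -0.09 over 612 long-arm genes and 0.01 over 838 short-arm genes. Of the long-arm genes 57 were called lower and 8 higher, against 25 and 27 on the short arm. The number of windows past the threshold was 37 without wild-type replicate 2, 100 without knockout replicate 1 and 19 without knockout replicate 2.

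**Figure D4:**
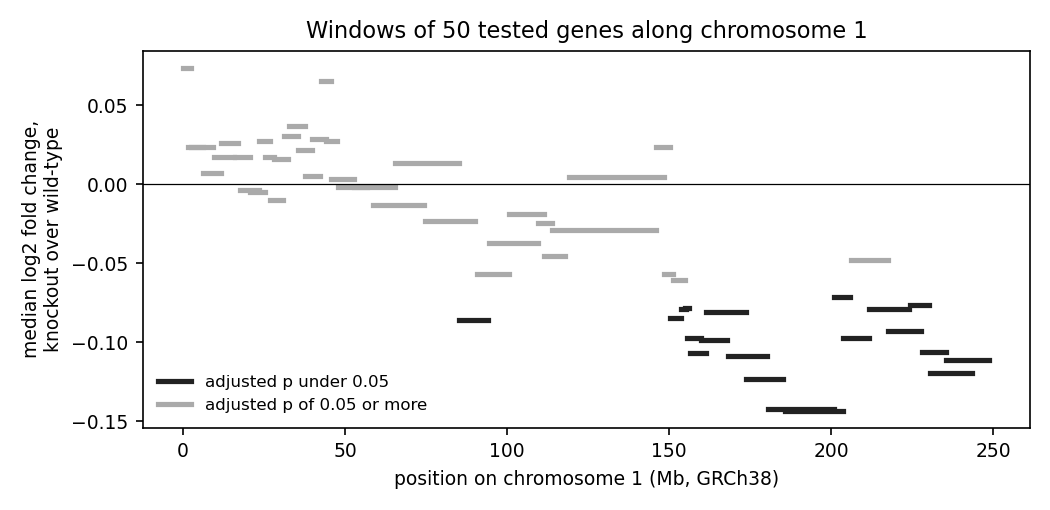
Median log2 fold change (knockout over wild-type, vertical axis) of windows of 50 neighbouring tested genes along chromosome 1 (Mb, GRCh38, horizontal axis), each bar spanning its window and black for adjusted p under 0.05. Long-arm windows lie as low as -0.14.

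A block of 6 adjacent tested genes at 15q15.3, chosen after its values were seen, was about doubled in knockout. It ran from PDIA3 to WDR76 (chromosome 15, 43746438 to 43868412). The disulfide isomerase gene PDIA3 went from 358 ± 10.5 to 702 ± 48.6 CPM (log2 fold change 0.97 ± 0.06). SERF2 (1.09 ± 0.06), HYPK (1.03 ± 0.23), the splicing factor gene MFAP1 (0.87 ± 0.07) and WDR76 (0.88 ± 0.07) rose as well. ELL3, with 16 counts in wild-type libraries, had 1.46 ± 0.50 and missed the threshold (adjusted p = 0.0723). Of the 20 tested genes flanking the block 0 were called higher, and their median was -0.03. The next gene downstream, FRMD5, had 0.00 ± 0.15. The next gene upstream, CATSPER2P1, had 0.78 ± 0.40 (adjusted p = 0.322) with 14 and 19 counts in wild-type and 21 and 30 in knockout, so the upstream edge was not resolved.

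**Figure D5:**
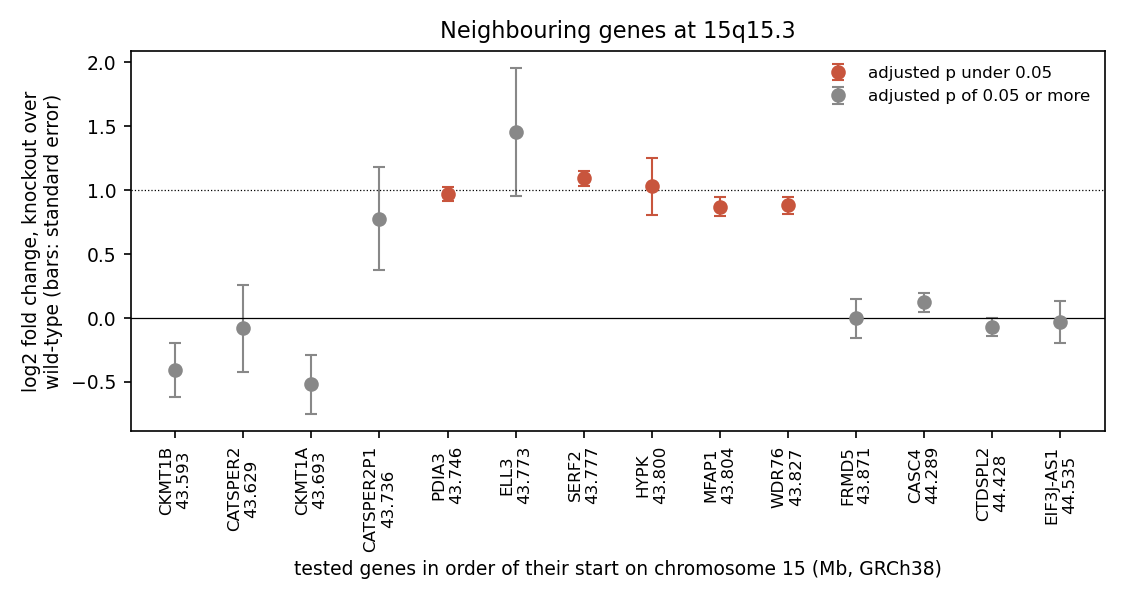
Log2 fold change with standard error (knockout over wild-type, vertical axis) of 14 tested genes in their order on chromosome 15 (start in Mb, GRCh38, horizontal axis), coloured where adjusted p was under 0.05. The 6 genes from PDIA3 to WDR76 lie at 0.87 to 1.46, and FRMD5 beside them at 0.00.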

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

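All alternatives were planned except 3: the microRNAs of at least 1000 CPM, the count without called genes near another, and the count without the genes of 1q and the 15q15.3 block, which were chosen after seeing the data. BCDIN3D was lower and past the threshold under every alternative, with log2 fold changes of -1.17 to -1.96. The number of higher genes was 497, against 767 with the date as a replicate block, 255 with DESeq2 and 246 to 686 when single libraries were left out. The number of lower genes was 568, against 331 with DESeq2 and 367 to 717 when single libraries were left out. With called genes dropped when another of the same direction lay within 1 Mb, 255 higher and 354 lower genes were left, by construction a smaller set. Without the genes of 1q and the 15q15.3 block 484 and 511 were left. All 1065 called genes were called with the replicate block too, and 583 of them with DESeq2. For microRNAs, 0 were higher in the main fit, against 2 without a filter, 3 with the stricter filter, 2 with the replicate block, 2 with DESeq2 and 0 to 2 when single libraries were left out. The number of lower microRNAs was 2, against 4 with the replicate block and 0 to 2 when single libraries were left out. Of the 5 gene lists past the threshold, 0 were so with an estimated correlation, 0 with the directional test of fry and 3 with its mixed test, and 3 to 7 lists passed when single libraries were left out. The heat shock list turned from up to down without wild-type replicate 2 (adjusted p = 0.0117, with a range of 0.0117 to 0.277 over the left-out libraries, and up past the threshold without wild-type replicate 1, adjusted p = 0.0382). The number of windows was 59, against 19 to 100 when single libraries were left out. The cause of these shifts was not tested. Over all named genes and alternatives, 99 values lost the threshold, 9 newly passed it and 0 reversed. NFKBIA and TRMT10C newly passed it with the replicate block. So did 43 members of the gene lists in all, and 0 lost it. The host gene correlation limited to abundant pairs was left with 5 pairs and gave no value. One count was worth 2.88 to 6.34 CPM in the small RNA libraries.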

Other observations

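Of the tests given here, the matched lists of 1q, its upper percentile and, for the 15q15.3 block, its pseudogenes and untested genes were fixed before their results were seen, and the others were chosen after seeing the data. Among 172 families of symbols with at least 10 tested members, 3 passed the threshold with camera: histones, protocadherins, which are neuronal adhesion molecules, and GALNT glycosyltransferases. None of the 3 passed with an estimated correlation (adjusted p = 0.998). Of 29 protocadherin genes 10 were lower and 1 higher, with PCDH17 at -5.21 ± 0.32 and PCDHB5 at -2.27 ± 0.22. Many protocadherin genes share exons or near-identical copies, so their counts are uncertain. Of 13 GALNT genes 4 were lower, GALNT5, GALNT14, GALNT16 and GALNT13.

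Small RNA counts of 1 name differed sharply between libraries of 1 group: miR-200a-5p had 2462 counts in knockout replicate 1 and 41 in knockout replicate 2, against 0 and 14 in wild-type. Histone genes lay mostly in the cluster on chromosome 6, and 16 other tested genes at 26 to 28 Mb of that chromosome had a median log2 fold change of 0.01. Other short genes, 109 with a span under 1500 bp that also passed a cut on mean abundance, had a median of 0.06.

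The 118 genes at least 8-fold lower in knockout may be genes silenced or lost in this clone. Their 225 nearest tested neighbours had a median log2 fold change of -0.0491, which argues against loss of a chromosome stretch as the whole cause. Such a loss stays open for part of them. Of the neighbours 22 (9.78%) were called lower against 3.80% of all placed genes. Of the 118 genes 8 lay next to another such gene, a number that 1.11% of 10000 random draws reached (median 2). These 8 were themselves counted among the 22, so the 2 findings overlap. PCDHAC1 and PCDHAC2, both among the 118, overlap in position, so lying side by side need not mean a lost stretch. The knockout libraries held 91.9% of the counts of the wild-type libraries, so low depth does not account for 8-fold falls. Among 5 marker lists the highest share of members called lower was 44.4%, for neural markers. That share counted falls of any size, and the neural ones ran from -0.21 (NES) to -1.32 (SYT1) on the log2 scale, short of 8-fold. It therefore cannot decide whether other cells were present in the wild-type cultures, which stays open. Loss of single genes stays open too, and silencing in the clone and loss of BCDIN3D cannot be told apart with 1 clone.

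Genes of 1q, an arm picked because its windows stood out in these same data, were lower by 0.09 in the median. Of 10000 lists matched on gene span and abundance none was as low, the lowest being at -0.0155. These lists drew genes from elsewhere in the genome, so they do not allow for the choice of the arm or for correlation between neighbours. The 1q median lay below that of 1p in both date pairs, with differences of -0.0663 and -0.129, so a single library does not account for all of it. The wild-type libraries themselves differed, with 1q minus 1p higher by 0.06 in replicate 2 than in replicate 1. Among genes above a log2 CPM of 4, the difference of the 75th percentiles (1q minus 1p) was -0.0919 and that of the medians -0.0983, as a shift of the whole arm would give. A copy change of the arm in a share of the cells may account for it, as a hypothesis, but the GC content of genes was not examined, so a bias with base composition stays open, and the link to BCDIN3D was not tested.

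The doubled block at 15q15.3 may be a copy gain in the knockout clone. The 3 pseudogenes named after its genes held in wild-type 0.44% of the CPM that the block gained, which argues against reads moved from them. In 10000 shuffles the longest run of neighbours over 1.5-fold higher was 6 genes (median 2), against 7 seen from CATSPER2P1 to WDR76. This argues against a chance run of 7. CATSPER2P1 was not called, however, and without it the run of 6 equals the longest in the shuffles. The shuffles also took genes as independent, although ELL3 and PDIA3 overlap in position. A copy gain of the block stays open, since its rising genes defined the block and the 2 untested genes inside it had 0 counts over the 4 libraries. A regulatory change shared by the neighbours stays open too, and neither was tested on DNA.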
